A study of Homo sapiens with 6 samples.

How the data were processed

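RNA of 3 parental and 3 cisplatin-resistant cultures of SCC9 cells was measured on one-colour (Cy3) oligonucleotide arrays with probes for mRNAs and lncRNAs. The authors deposited a table of normalized intensity per transcript identifier, made with RMA (background correction, normalization between arrays and summary of the probes of a transcript) per the submitters' processing notes. The parameters of RMA, and the filter that left fewer identifiers in the table than on the array, are not given in the sources used here. The values were on a linear scale, although log2 values had been assumed when the design was written, so log2 was taken before all further steps. Unnormalized scanner intensities per spot, written by NimbleScan 2.5.26 per the file headers, were used for replicate 1 of each group only. Scanner values of the other 4 arrays were not used here.

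Groups were taken from the sample labels, and 0 value columns belonged to no sample. Rows with an NM accession were taken as mRNA (18473), and the other 23679 rows as lncRNA. The latter held 15071 rows with an ASLNC identifier, 121 with an HMlincRNA identifier, 6953 with other accessions, and 1347 exon and 187 position identifiers, none of which could be matched to gene names. The accessions of 17747 mRNA rows were matched to current symbols through a RefSeq gene table of the assembly GRCh38.p14, and 726 were not matched. The genome build behind the array design is not given in the sources used here. Gene order along chromosomes was taken from the same table.

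Each scanner file held 137604 spots, 6186 of them random-sequence probes, and 49389 transcript identifiers. The scanner values correlated best with the table column of their own sample, with r across rows of 0.962 for parental and 0.964 for resistant replicate 1. The background was set at the 95th percentile of the random probes, carried to the scale of the table through rows with a single probe near that level. This gave an intensity of 113 (log2 6.82) from the parental array and 95.4 from the resistant array, and the higher was used for all 6 arrays, 4 of which have no random-probe values here. A change between a group below this level on all its arrays and the other group is given as "at least" a fold, the other group's mean against the background. Where a named gene was under it on some arrays of a group, the change is given with those values set to the background, unless it is called fitted. Of the rows, 42.2% were above background on all arrays and 26.4% on none.

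Resistant and parental arrays were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a constant variance prior (4 residual and 3.29 prior degrees of freedom, prior SD 0.486), no filter on low values, and Benjamini-Hochberg adjustment over all 42152 rows. A row was called at an adjusted p under 0.05, and all tests were two-sided. Gene lists with at least 5 measured genes were tested with camera of limma (preset correlation 0.01) on the 14294 named genes, each represented by its row with the highest mean, with adjustment over the 44 lists tested. Of the 45 lists fixed, that of lncRNAs known from cancer had too few matched names and was not tested. The comparison, its threshold, the gene lists, most of the other settings tried and the rule for naming genes were fixed before the data were examined.

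The rule named, among called mRNA rows with all 3 arrays of one group above all 3 of the other and a mean in the higher group above the median of all rows, the 10 largest rises and the 10 largest falls by fitted change. It named the 5 largest rises and the 5 largest falls among lncRNA rows in the same way. It also named up to 4 called members of each list by size of change, and all members of the lists of platinum and copper transport, metallothioneins and ABC drug efflux transporters. Other genes are said to be picked after their values were seen.

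The groups share replicate numbers, and no label says what a number stands for. Whether same-numbered samples deviated together was checked by correlating deviations from the group means across rows, which gave r of 0.361, 0.267 and 0.176 for numbers 1, 2 and 3. All were above 0.1, the level set for treating the numbers as pairs, so the pairing comes from the data and not from the design. The 3 values are not independent, since deviations cancel out within a group. For parental 3 with resistant 2 and parental 2 with resistant 3, r was 0.003 and −0.020 over all rows. Among rows above background it was 0.155 and 0.122. Pairing of numbers 2 and 3 is therefore less sure than that of number 1. Values with the replicate number as a block stand beside a result where the block changed its call or moved a count by more than 1.5 times.

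The other settings fixed in advance were median centring of each array, quantile normalization, leaving out the lowest 30% of rows, eBayes with trend and robust, array weights, the replicate block, leaving out each array in turn, adjusted p under 0.01, a 2-fold minimum, 1 row per gene, the mean of a gene's rows, camera with an estimated correlation, and fry. Settings chosen after the data were seen were leaving out both replicate 1 arrays, keeping rows above background on at least 3 arrays, and counting only ASLNC and HMlincRNA rows. Correlations of antisense pairs were not computed, since the lncRNA rows have no names.

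The comparison was tested on simulated data of 42152 rows with the measured spread and 3 arrays per group. Changes of 1, 2, 4 and 6 on the log2 scale were given to 50 rows each, drawn from all rows. They were called in 0%, 20%, 66% and 92% of the changed rows, and 4.30% of the calls (4 rows) were false. A list raised by 1.5 was called by camera, with 0 other lists. The simulated rows varied independently of each other, unlike genes on the arrays. The 0 thus does not bound false calls of lists in the measured data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.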

Results

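SCC9, an established squamous carcinoma line from a human tongue tumour, was compared with a derivative made resistant to cisplatin, a platinum drug that crosslinks DNA. The resistant cells had been grown in rising amounts of the drug, starting at 1e-07 M and ending at 1e-05 M. Whether cisplatin was present at harvest is not given in the sources used here. Both kinds of cell were kept in medium with 10% serum and 400 ng/ml of the glucocorticoid hydrocortisone. RNA of 3 parental and 3 resistant cultures, which the design text calls biological replicates, was hybridised to 6 one-colour arrays that carry mRNA and lncRNA probes. The value table held 42152 rows, of which 18473 had an mRNA accession. The other 23679 are called lncRNA rows, although no source used here classed each of them, and some may be parts of mRNAs. Of the mRNA rows, 17747 matched a gene symbol and covered 14294 genes. The median intensity of an array lay between 141 in parental replicate 2 and 151 in resistant replicate 1, and between 54.9% and 56.5% of the rows of an array were above the background of random probes. The number of arrays limits the precision of all values below. The sample labels name no separate selections for resistance among the 3 resistant cultures. The tests thus rest on the spread between cultures and do not show whether another selection would give the same changes.

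The comparison asked which mRNAs and lncRNAs differed between resistant and parental SCC9 cells. Among 44 gene lists tested, the 2 with the smallest adjusted p were keratinocyte differentiation genes, which fell, and cytokine genes and other targets of NF-kB, which rose. The structural proteins SPRR1B, SPRR1A and KRT1 had the largest falls among the mRNAs. With values under background set to background, they fell by 6.85, fell by 6.24 and fell by 6.17 on the log2 scale. The cytokines CSF2 and CXCL8 and the cyclin CCND2 were among the 10 largest rises by fitted change. By limma at a Benjamini-Hochberg adjusted p under 0.05, 1180 rows changed, of which 671 rose and 509 fell. The smallest fitted change among them was 1.38 on the log2 scale. With values under background set to it, 988 of the 1180 rows differed by at least 2-fold and 192 by less, 45 of which were under background on all 6 arrays. The calls fell on 598 named genes, 315 with a row that rose and 284 with a row that fell, 1 gene having rows in both directions.

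The number of calls depended on how the spread between arrays was treated. Deviations of same-numbered samples correlated, most strongly for number 1. With the replicate number as a block limma called 562 rows, 540 of them among the 1180. Leaving out parental replicate 1, 2 or 3 gave 778, 346 or 383 rows, and leaving out resistant replicate 1, 2 or 3 gave 640, 265 or 225 rows. Without both replicate 1 arrays limma called 0 rows (7896 at an unadjusted p under 0.05), and 4328 rows when its variance prior followed the signal level and was made robust. In all 1180 rows the 3 arrays of one group lay above the 3 of the other, so their sign could not change in these fits. The balance of the calls did turn: 56.9% of the 1180 calls were rises, against 44.2% without resistant replicate 2 and 43.1% without resistant replicate 3. Of the 78 called rows chosen by the naming rule, 52 kept their call with the block, 0 without both replicate 1 arrays, and between 39 (without resistant replicate 3) and 60 (without resistant replicate 1) when an array was left out.

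Both replicate 1 arrays lay apart from the other 4 arrays. The first principal component of the 22676 rows used, with 49.5% of the variance, separated parental from resistant arrays. The second, with 26.1%, put parental replicate 1 at 64.6 and resistant replicate 1 at 69.3, and the other 4 arrays between −44.4 and −23.2. In a comparison of the replicate 1 arrays with the other 4, limma called 0 rows (7252 at an unadjusted p under 0.05), and camera called 0 gene lists. Correlations across rows, which are not independent replicates, were 0.968 between resistant replicates 2 and 3 and 0.949 between parental replicates 2 and 3, against 0.896 between the replicate 1 arrays of the 2 groups.

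**Figure D1:**
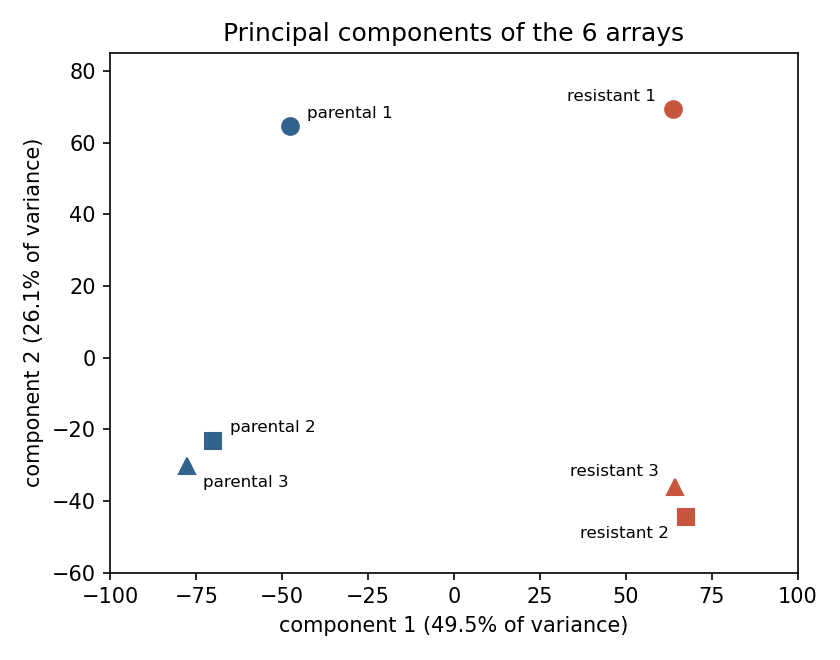
Principal components of the 6 arrays, computed from log2 intensities. The horizontal axis is component 1 (49.5% of the variance) and the vertical axis component 2 (26.1%), both in units of log2 intensity, blue points are parental arrays, red points are resistant arrays, and shapes mark the replicate number. Component 1 separates the groups, and on component 2 parental replicate 1 (64.6) and resistant replicate 1 (69.3) lie apart from the other 4 arrays.

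Genes of keratinocyte differentiation fell in resistant cells. Of 39 measured members of this list, 25 fell, 1 rose and 13 were not called, with a median log2 change of −2.53, or −1.72 with genes at background in a group set to their bound. Camera gave an adjusted p of 1.41e-18, and 0.0474 with an estimated correlation, but 0.460 with the estimated correlation and the replicate number as a block. Adjusted over the list alone, 29 fell and 2 rose. The small proline-rich proteins SPRR1A and SPRR1B are cross-linked into the cornified envelope. SPRR1B fell from 14.35 ± 0.14 to 6.98 ± 1.72 log2 intensity (mean ± SD, n = 3), a fitted log2 change of −7.37 ± 0.78 (SE; limma adjusted p = 0.00667). SPRR1A had a fitted change of −7.48 ± 1.47 (SE; limma adjusted p = 0.0472). Both genes, and KRT1 and KRT4, keratins of suprabasal layers of skin and mucosa, were above background on 1 of 3 resistant arrays. With values under background set to it, KRT1 fell by 6.17 and KRT4 fell by 5.45. The mucosal keratin KRT13 fell by 4.73. The envelope precursor involucrin, IVL, was at least 5.25-fold lower in resistant cells (limma adjusted p = 0.00607). The member that rose was the epithelial keratin KRT80, by 2.42, which was not called without resistant replicate 3. KRT13, IVL and KRT80 were picked after their values were seen. With the replicate number as a block, 18 members of the list fell, and SPRR1A and KRT1 had adjusted p of 0.0821 and 0.0616. SPRR1A, KRT1, KRT6A and the other 7 largest falls all had their highest resistant value in replicate 1, and SPRR1A was at 10.69 there against 4.30 and 5.62 in the other 2 resistant arrays. Members of the SPRR family are so similar in sequence that cross-hybridisation between them was not excluded.

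Basal keratinocyte genes also fell, although not all of them. Of 21 measured members, 10 fell, 0 rose and 11 were not called, with a median log2 change of −2.16, or −1.76 at the bound. Camera gave an adjusted p of 1.57e-10, and 0.0428 with an estimated correlation, but 0.419 with the estimated correlation and the block. Adjusted over the list alone, 15 fell. TP63, the transcription factor that specifies stratified epithelia, fell by 2.47 ± 0.34 (SE; limma adjusted p = 0.0150, or 0.0504 with the replicate number as a block). KRT15, a keratin of basal cells, fell by 3.47, and COL17A1 and DST, both parts of hemidesmosomes, fell by 2.16 and 2.22. KRT16 fell by 4.67 and KRT6B fell by 3.66. Both are keratins of activated keratinocytes, and KRT6A, KRT6B and KRT6C are near-identical. KRT5, the basal type II keratin, was measured at 15.78 ± 0.13 in parental and 15.24 ± 0.11 in resistant cells (mean ± SD, n = 3; limma adjusted p = 0.402). Its usual partner KRT14 differed by −4.72 ± 1.22 (SE; limma adjusted p = 0.104), with 13.94 in resistant replicate 1 against 9.05 and 9.23 in the other 2. TP63, COL17A1 and DST were not called without parental replicate 2 or 3 or resistant replicate 2 or 3, and KRT16 was not called without resistant replicate 3. KRT14 was called only without resistant replicate 1. TP63, KRT15, KRT5, KRT14, COL17A1 and DST were picked after their values were seen.

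**Figure D2:**
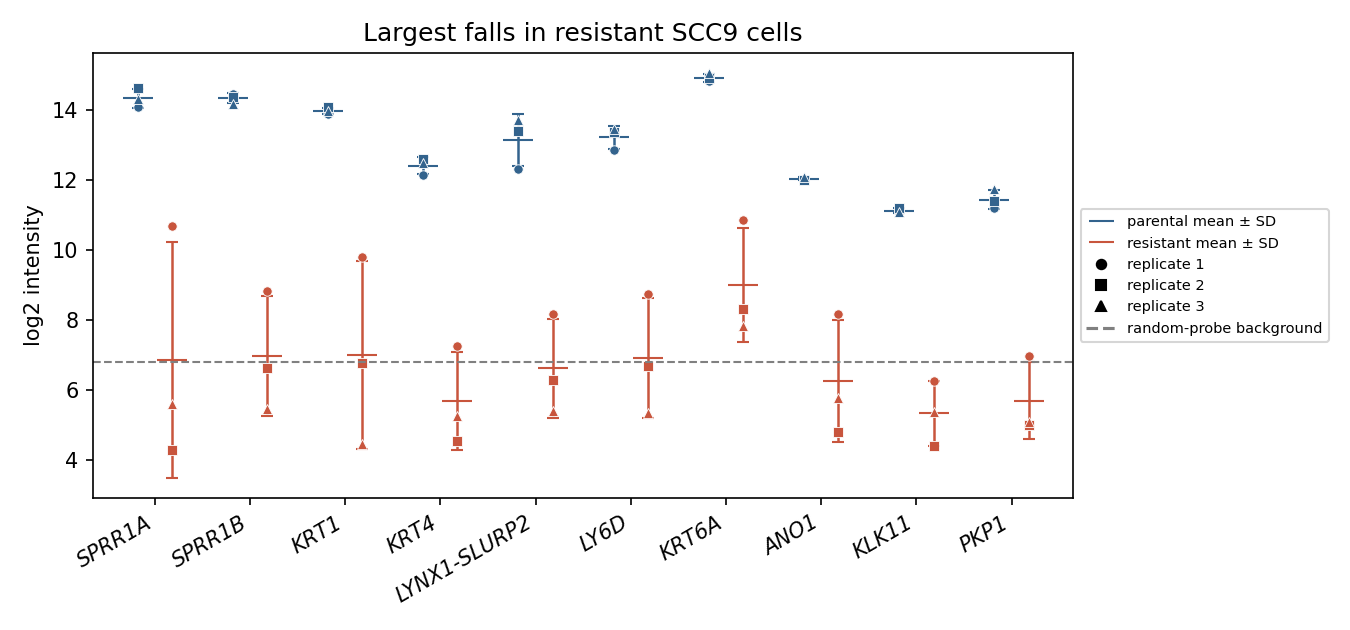
Log2 intensity of the 10 mRNAs with the largest falls, on the vertical axis, for each gene on the horizontal axis. Points are arrays (blue parental, red resistant, shape by replicate number), horizontal strokes and bars are means ± SD of 3 arrays, and the dashed line is the random-probe background at log2 6.82. The red circles, resistant replicate 1, are the highest resistant values of all 10 genes, and KLK11 is below background on all 3 resistant arrays.

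Other large falls included a pair of Ly6 proteins, a chloride channel, a protease and a desmosomal protein. LYNX1-SLURP2, LY6D, ANO1 and PKP1 were above background on 1 of 3 resistant arrays, and their falls and that of DSG3 are given with values under background set to it. LYNX1-SLURP2 and LY6D, members of the Ly6 family, fell by 5.87 and fell by 5.77. ANO1, a calcium-activated chloride channel, fell by 4.77, and the kallikrein protease KLK11 was at least 19.9-fold lower, being below background on all 3 resistant arrays. The desmosomal plaque protein PKP1 fell by 4.58 (limma adjusted p = 0.00551, from the fitted change), and of the desmosomal cadherins DSC3 fell by 3.58 and DSG3 fell by 3.07. DSP changed by −2.68 (limma adjusted p = 0.0126, or 0.0545 with the replicate number as a block). DSG3 was called only in the fit without resistant replicate 1 among those that left out an array, and DSP only in those without replicate 1 of either group. The list of 32 epithelial junction genes was not called as a whole (camera adjusted p = 0.303), with 6 members that fell and 1 that rose, the tight junction protein OCLN, by at least 2.31. OCLN, picked after its value was seen, lost its call with the block (adjusted p = 0.0655) and whichever array was left out. Of the 10 largest falls by fitted change, KLK11, PKP1, SPRR1B, KRT4 and LYNX1-SLURP2 kept their call in all 6 fits that left out an array. LY6D and KRT6A were not called without resistant replicate 2, ANO1 was not called without parental replicate 2 or 3 or resistant replicate 3, and SPRR1A and KRT1 were called only where resistant replicate 1 was the array left out.

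Cytokine genes and other NF-kB targets rose in resistant cells. Of 30 measured members, 16 rose, 0 fell and 14 were not called, with a median log2 change of 1.69, or 1.63 at the bound. Camera gave an adjusted p of 5.83e-18, and 0.0428 with an estimated correlation, but 0.419 with the estimated correlation and the block. Adjusted over the list alone, 22 rose and 1 fell. CSF2, the growth factor GM-CSF, was at background in parental cells and at least 24.3-fold higher in resistant cells (limma adjusted p = 0.00422), and the neutrophil chemokine CXCL8 was at least 13.1-fold higher. IL6 rose from 8.87 ± 0.07 to 12.49 ± 0.04 log2 intensity (mean ± SD, n = 3), by 3.62 ± 0.27 (SE; limma adjusted p = 0.00433). LCN2, the iron-carrier lipocalin, rose by 3.96, TNF was at least 9.02-fold higher, and complement C3 rose by 3.21. CXCL1 and CXCL2, which are similar in sequence, rose by 2.67 and 2.58. The member that fell when adjusted over the list alone was IL1RN, the antagonist of the interleukin 1 receptor, at least 3.05-fold lower in resistant cells (limma adjusted p = 0.0608 over all rows). NFKB1 and RELB, subunits of NF-kB itself, differed by 0.14 ± 0.27 and −0.23 ± 0.39 (SE; limma adjusted p of 0.859 and 0.841). With the replicate number as a block, 10 members rose and 1 fell, IL1RN (adjusted p = 0.0473). CSF2, CXCL8, IL6, LCN2, TNF, C3 and CXCL1 were called in all 6 fits that left out an array, and CXCL2 was not called without parental replicate 3 or resistant replicate 2 or 3. TNF, C3, CXCL1, CXCL2, IL1RN, NFKB1 and RELB were picked after their values were seen, and RELB changed sign in at least 1 of the other settings.

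The 10 largest rises of mRNAs by fitted change fell in several kinds of gene. COXFA4L3, also known as C15orf48, a mitochondrial protein related to a cytochrome c oxidase subunit, was at background in parental cells and at least 41.4-fold higher in resistant cells (limma adjusted p = 0.00200). NOG, a secreted antagonist of BMPs, was at least 18.5-fold higher, and the serine protease TMPRSS2 at least 17.5-fold. DMBT1, a mucosal scavenger receptor, was at least 13.6-fold higher and the incretin hormone GIP at least 12.9-fold. CCND2, a cyclin of the G1 phase, was measured in both groups and rose from 9.42 ± 0.51 to 14.39 ± 0.13 (mean ± SD, n = 3), by 4.96 ± 0.35 (SE; limma adjusted p = 0.00433). CDH5, the cadherin of endothelial cells, was at least 5.69-fold higher, and the transcription factor CREB5 at least 3.98-fold. DMBT1 was not called with the replicate number as a block (adjusted p = 0.0501), nor without resistant replicate 2 or 3. The other 9 of these genes were called in all 6 fits that left out an array. In all, 115 named rows rose from background on every parental array, and 79 named rows fell to background on every resistant array.

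**Figure D3:**
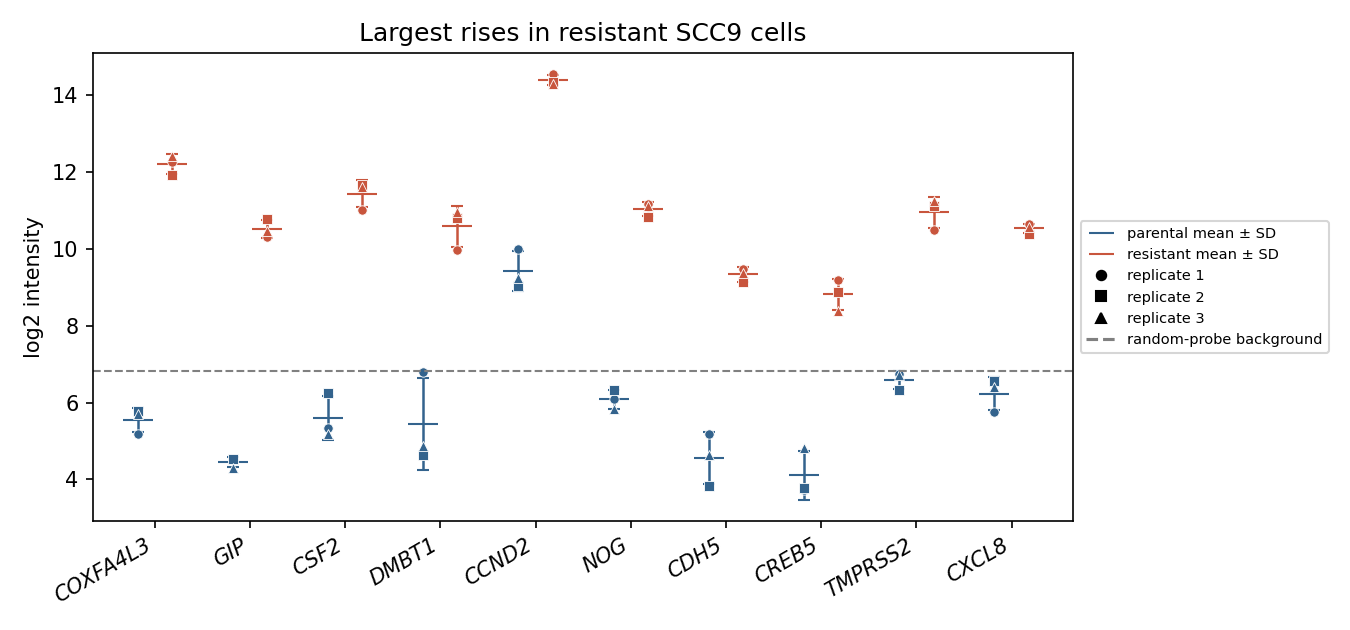
Log2 intensity of the 10 mRNAs with the largest rises, on the vertical axis, for each gene on the horizontal axis. Points are arrays (blue parental, red resistant, shape by replicate number), horizontal strokes and bars are means ± SD of 3 arrays, and the dashed line is the random-probe background at log2 6.82. All genes but CCND2 lie below background on the 3 parental arrays, so that their folds are lower bounds.

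Matrix and adhesion genes moved in both directions. Of 29 mesenchymal genes linked to epithelial-mesenchymal transition, 4 rose, 0 fell and 25 were not called, with a median log2 change of 0.53, or 0.28 at the bound (camera adjusted p = 1.17e-05, but adjusted p = 0.128 with an estimated correlation). Adjusted over the list alone, 11 rose. The matricellular proteins CCN1 and SPARC rose, CCN1 by at least 3.83 with values under background set to it and SPARC by 3.48 ± 0.34 (SE; limma adjusted p of 0.00707 and 0.00551), and fibronectin, FN1, rose by 2.93. The receptor tyrosine kinase AXL differed by 1.46 (limma adjusted p = 0.0428, 0.0842 with the replicate number as a block, and above 0.05 whichever array was left out, at most 0.176). Matrix metalloproteinases and plasminogen genes were not called as a list (camera adjusted p = 0.515), with 3 members that rose and 6 that fell of 22. The collagenases MMP1 and MMP13 were at least 11.2-fold and 10.5-fold lower in resistant cells, and the stromelysin MMP10, above background on 1 resistant array, was at least 18.1-fold lower. Matrilysin, MMP7, rose by 4.13 ± 0.37 (SE; limma adjusted p = 0.00486). In the TGF-beta and BMP list, which was not called (camera adjusted p = 0.0605), TGFB2 was at least 8.59-fold higher, BMP7 at least 8.07-fold lower, and ID1, a target of BMP signalling, fell by 3.50. TGFB2 was not called without resistant replicate 3.

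Interferon-stimulated and antigen presentation genes rose as lists by small amounts. Of 38 interferon-stimulated genes, 3 rose and 0 fell, with a median log2 change of 0.50 and 32 members higher in resistant cells (camera adjusted p = 1.17e-05, but adjusted p = 0.201 with an estimated correlation). The members that rose were IFI44L by at least 2.01 with values under background set to it, MX2 by 1.80 and GBP1 by 1.44, and with the replicate number as a block their adjusted p were 0.0915, 0.0682 and 0.0853. IFI44L and GBP1 also lost their call whichever array was left out, and MX2 in all such fits but that without resistant replicate 1. Of 18 antigen presentation genes, 1 rose, with a median of 0.34 (camera adjusted p = 0.000912, but adjusted p = 0.392 with an estimated correlation). It was the MHC class II chain HLA-DRB1, at least 4.37-fold higher (limma adjusted p = 0.00845), which was not called without resistant replicate 2 or 3. Adjusted over the list alone, 6 interferon-stimulated and 5 antigen presentation genes rose.

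Notch, cholesterol, oxidative phosphorylation and NRF2 lists were lower in resistant cells, and none of them was called with an estimated correlation. Of 19 Notch pathway genes, 4 fell and 1 rose, with a median of −1.15, or −0.32 at the bound (camera adjusted p = 0.0316, 0.0597 with the replicate number as a block, and adjusted p = 0.386 with an estimated correlation). HES2 fell by 4.02 ± 0.29 (SE; limma adjusted p = 0.00433), the receptors NOTCH3 and NOTCH1 by 2.69 and 1.99, and the ligand JAG1 by 2.40. RBPJ, the DNA-binding partner of Notch, picked after its value was seen, rose by 1.91. NOTCH1 and RBPJ had adjusted p of 0.0517 and 0.0707 with the block. Of these 5 genes, HES2 alone was called in all 6 fits that left out an array; NOTCH3 kept its call in 1, NOTCH1 in 2, JAG1 in 4 and RBPJ in 0. The Notch list was also not called without both replicate 1 arrays (camera adjusted p = 0.0638), without parental replicate 3 (0.0522) or without resistant replicate 1 (0.0791). Of 20 genes of cholesterol synthesis, 17 were lower, with a median of −0.57 (camera adjusted p = 0.00220, but adjusted p = 0.189 with an estimated correlation). Of 28 genes of oxidative phosphorylation, 27 were lower and 0 were called, with a median of −0.51 (camera adjusted p = 0.000540, but adjusted p = 0.201 with an estimated correlation). Of 25 NRF2 targets and glutathione genes, 2 fell, with a median of −0.41 (camera adjusted p = 0.0316, 0.0622 without parental replicate 2, and adjusted p = 0.216 with an estimated correlation). These were PIR, by 2.16, and AKR1C1, by 1.72, and AKR1C1 had an adjusted p of 0.0703 with the block. PIR was called in 1 of the 6 fits that left out an array, that without resistant replicate 1, and AKR1C1 in 0.

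**Figure D4:**
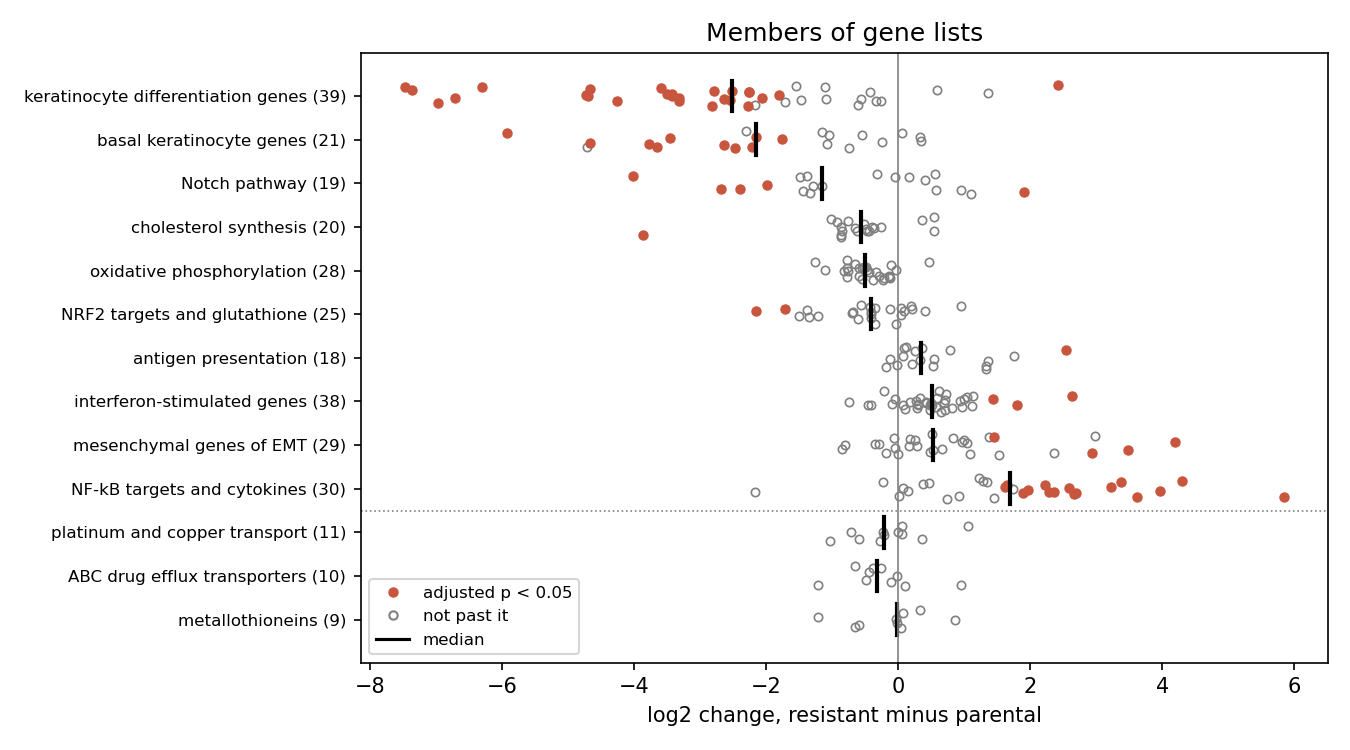
Log2 change of each measured member, resistant minus parental, on the horizontal axis, for the 10 gene lists called by camera (above the dotted line) and 3 lists of drug transport and metal binding (below it), with the number of members in brackets. Filled red points passed the limma adjusted p, open grey points did not, and black strokes are medians. Keratinocyte differentiation genes lie furthest to the left by their fitted changes (median −2.53) and NF-kB targets furthest to the right (median 1.69).

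Lists tied to platinum handling were not called. Of 11 platinum and copper transport genes, 0 were called, with a median log2 change of −0.22, or 0 at the bound (camera adjusted p = 0.755). LRRC8D, above background on 1 parental array only, had a fitted difference of −1.03 (SE 0.37, limma adjusted p = 0.224). The copper importer SLC31A1, which also takes up cisplatin, differed by −0.28 ± 0.27 (SE; limma adjusted p = 0.685), and the copper exporter ATP7B by a fitted 1.05 ± 0.29 (limma adjusted p = 0.127), while its relative ATP7A was at background on all 6 arrays. Of 9 metallothionein genes, 0 were called, with a median of −0.02, or 0 at the bound (camera adjusted p = 0.755). MT1H, above background on 1 parental array only, had a fitted difference of −1.22 (SE 0.53, limma adjusted p = 0.318). MT2A, a metal-binding protein, was at 14.29 ± 0.14 in parental and 14.27 ± 0.24 in resistant cells (mean ± SD, n = 3; limma adjusted p = 0.987). Of 10 ABC drug efflux transporters, 0 were called, with a median of −0.33, or −0.19 at the bound (camera adjusted p = 0.506), and ABCC2, an exporter of drug conjugates and under background on 2 resistant arrays, had a fitted difference of −1.22 ± 0.66 (SE; limma adjusted p = 0.436). ABCC3 differed by 0.95 (SE 0.43, limma adjusted p = 0.346). Members of these lists without a measured row were not tested. They were ABCB1, ABCB11, ABCC6, ABCC11 and ABCG2 of the efflux list, and SLC22A2, SLC22A3, CCS and ATP11B of the platinum list. MT1G, MT1M and MT1X had no measured row either. DNA repair lists were not called, nucleotide excision repair having a median of −0.29 over 21 genes (camera adjusted p = 0.303) and the Fanconi and homologous recombination list 0.05 over 31 genes, or 0.01 at the bound (0.755). With arrays simulated at the measured spread, a change of 1 on the log2 scale was called in 0% of rows and a change of 2 in 20%. Those rows were drawn from all rows, 50 for each size, so the shares need not hold for these genes. Far fewer rows changed in the simulation than were called in the data. The Benjamini-Hochberg adjustment was therefore stricter there, and the shares may be too low for the measured comparison. In the measured data the smallest fitted change called in any row was 1.38, so a shift of 1 in a single gene would mostly have been missed.

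Rows without an mRNA accession changed less often than mRNA rows. Among lncRNA rows, 453 changed (293 rose and 160 fell, 1.91% of rows), and among mRNA rows 727 (378 rose and 349 fell, 3.94% of rows). With the replicate number as a block the counts were 199 and 363. Weighted to the signal levels of the mRNA rows, 2.44% of lncRNA rows changed, and the ratio of the shares was 1.62, with a 95% bootstrap interval of 1.42 to 1.85. The interval treats rows as independent, which they are not. By fitted change, which rests on parental values under background, ASLNC08201 and ASLNC05042 were among the 5 largest rises of lncRNA rows, at least 8.23-fold and at least 10.8-fold (limma adjusted p of 0.00422 and 0.00433). ASLNC24439, above background on 1 resistant array, was at least 31.1-fold lower (limma adjusted p = 0.00433). ASLNC02979 changed by −5.28 ± 0.92 (SE; limma adjusted p = 0.0318), but its adjusted p was 0.0592 with the block, and it was called in only 1 of the 6 fits that left out an array, that without resistant replicate 1. The files do not pair these identifiers with gene names. Of the 453 calls, 362 were rows whose identifier starts with ASLNC or HMlincRNA.

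Markers of other cell types were not called as lists. Camera adjusted p was 0.737 for 11 endothelial, 0.918 for 10 fibroblast, 0.755 for 15 leukocyte, 0.515 for 9 melanocyte and neural crest, and 0.755 for 13 glandular and cervical epithelium markers. Of these, 9, 7, 5, 6 and 11 were at background in a group, which limits the tests. Adjusted over the list alone, 1, 1, 0, 2 and 1 rose, and 1 fibroblast and 1 glandular marker fell. CDH5 was the endothelial marker that rose, and the amylase AMY1A, a glandular marker, was at least 2.06-fold higher (limma adjusted p = 0.0359, or 0.0748 with the replicate number as a block, and not called whichever array was left out). Among 12 housekeeping genes 0 were called, with a median log2 change of 0.03, or −0.00104 at the bound.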

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

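The comparison and test described here were chosen only after the scanner values had been looked at. The scanned arrays of parental and resistant replicate 1 hold 7237 transcript identifiers that are not in the table of normalized intensities and enter no comparison above. Of these, 0.636% (46 identifiers) lay above the 99th percentile of the random probes on both arrays, against 0.339% of the random probes themselves. The shares differed by Fisher's exact test (two-sided, p = 0.0189), but an identifier is a mean over its probes and a random probe is a single spot, so that the shares are not fully comparable. Whether these identifiers are transcripts with signal remains open. The rule that left them out is not given in the sources used here, no biological explanation was tested, and no change between groups was computed for them.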

How the results depend on the processing

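Alternatives without both replicate 1 arrays, with rows above background on at least 3 arrays, or with ASLNC and HMlincRNA rows only were chosen after the results were seen; the others were planned. In each alternative fit to all rows or to a filtered set, all of the 1180 called rows that were tested kept their sign. In all 1180, the 3 arrays of one group lay above the 3 of the other. Only median centring and quantile normalization could thus have changed a sign. Median centring, quantile normalization, a 2-fold minimum on the fitted change and 1 row per gene kept the counts of changed rows, mRNA rows and lncRNA rows within 1.5 times of 1180, 727 and 453. These counts rose to 1961, 1185 and 776 without the lowest 30% of rows and to 2420, 1488 and 932 with rows above background on at least 3 arrays, where fewer rows were tested. They were 2109, 1359 and 750 with trend and robust eBayes and 1945, 1158 and 787 with array weights, and the cause was not tested. They fell to 256, 177 and 79 at an adjusted p under 0.01, by construction. With the replicate block they were 562, 363 and 199, and the cause was not tested. The block ended the calls of 26 of the 78 called rows named by rule, of the Notch list, and of TP63, OCLN and RBPJ among genes picked later; it added a call of IL1RN and changed no other call of a named gene or list. Without both replicate 1 arrays limma called 0, 0 and 0 rows (7896 at an unadjusted p under 0.05, smallest adjusted p 0.0606). With trend and robust eBayes as well it called 4328, but that setting also raised the count on all arrays to 2109, and the cause was not tested. With 1 array left out, where fewer samples were tested, these counts ranged from 225 (without resistant replicate 3) to 778 (without parental replicate 1), from 153 to 489 and from 72 to 289, with the same arrays at the ends. Called gene lists, 10 by camera, ranged from 9 to 11 with 1 array left out, and numbered 3 with an estimated correlation and 18 by fry, which tests each list without comparing it with other genes. The cause of the lower count was not tested. With the block and an estimated correlation together, 0 lists were called (adjusted p of 0.460 for keratinocyte differentiation and 0.419 for basal genes and NF-kB targets). The NRF2 list was not called without the lowest 30% of rows (0.0759) or with rows above background on at least 3 arrays (0.0865). Correlations of antisense pairs and a background correction of the scanner values were not run. Signal over background limits the folds: 26.4% of rows were above background on no array. With genes at background in a group set to their bound, none of the medians of the 10 called lists changed direction.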

Other observations

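The tests of families, of a non-squamous line, of shared handling, of parental and erythroid RNA, and of splits of the samples by counts of rows were chosen only after the results were seen. Of 262 families of at least 8 genes with a common symbol stem, camera called 10 with the preset correlation, 5 in each direction, and 0 with an estimated correlation (smallest adjusted p 0.529). The 3 with the smallest adjusted p at the preset correlation were SPRR, SERPINB and KLK. Of 8 SPRR genes 7 fell, with a median log2 change of −4.12 (camera adjusted p = 1.49e-09), of 12 KLK genes 6 fell (median −2.17, 1.56e-06) and of 12 SERPINB genes 6 fell (median −1.86, 4.57e-07). SPRR2B and KLK8 fell by 4.44 and fell by 4.33, SERPINB13 was at least 3.57-fold lower, and all 3 were called whichever array was left out. Among families that rose, 5 of 12 CXCL genes were called (median 0.97, camera adjusted p = 0.0352). The MRPL family, for proteins of mitochondrial ribosomes, was lower (median −0.44, camera adjusted p = 0.0197), with 0 of its 44 genes called. With genes at background in a group set to their bound, the medians of SERPINB and CXCL genes were −1.47 and 0.39, and those of SPRR, KLK and MRPL genes were unchanged. Of the genes in these families, 4 SPRR, 4 KLK, 3 SERPINB and 6 CXCL genes were also in the fixed lists.

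Hypoxia and glycolysis genes were not called as a list (camera adjusted p = 0.506), but of 26 measured, 5 fell and 0 rose, or 6 and 3 adjusted over the list alone. ALDOC, PFKFB4 and NDRG1 lost their call whichever array was left out, and with the replicate number as a block (limma adjusted p of 0.0774, 0.0757 and 0.0856). The carbonic anhydrase CA12 was at least 5.00-fold lower in resistant cells and was called in all 6 fits that left out an array.

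Squamous genes fell and cytokine genes rose together in the resistant arrays. The tables argue against the authors' normalization as the source: in unnormalized values of replicate 1 the keratinocyte differentiation list changed by a median of −1.60 relative to all rows (quartiles −2.50 and −0.71). They argue against an admixture of endothelial cells, fibroblasts or leukocytes, since 1 of 16 of their markers at background in parental arrays, 6.25% (95% interval 0.158 to 30.2), was above it on all resistant arrays. They argue against a non-squamous line in place of the resistant one, since 18 of 20 basal keratinocyte genes, 90%, stayed above background. A shift of the resistant line away from the squamous state, or the growth of a clone or of another squamous line, remains open and was not tested.

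The replicate 1 arrays of both groups stood apart from the others, and the design names no biological difference between the numbers. Of 502 rows that deviated at least 4-fold in parental replicate 1, 78.3% (95% interval 74.4 to 81.8) deviated the same way in resistant replicate 1, and rows are not independent. Handling shared by same-numbered samples may be the source, but any source common to both arrays would give such a share. The share thus restates that both arrays stood apart and does not favour handling. Parental RNA in resistant replicate 1 at the share seen for KRT14, 34.7%, is argued against by the other genes that fell, with an upper quartile of 5.82% of the parental level. Over the 38 genes the share ran from −0.456% to 59.0%, with 4 genes under 1%, so no single share held for all. A share nearer their median of 3.53% (36 of 38 genes above 0) remains open. The genes were chosen for high parental and low resistant values in replicates 2 and 3, which favours an excess in resistant replicate 1. In most of them parental replicate 1 was below the mean of the other 2 parental arrays. A deviation in the same direction on both replicate 1 arrays would therefore not give the excess in those genes. Erythroid RNA on both arrays cannot be told apart from other sources, its list having been chosen after globin genes were seen. Of 12 erythroid markers at background on the other 4 arrays, 8 (66.7%, 95% interval 34.9 to 90.1) were above it on both. This compares with 5.65% of all such genes, 0 of 7 hepatocyte and 2 of 2 luminal breast markers. Of all 25 erythroid markers measured, 15 were higher on both replicate 1 arrays than on all others, against 15.2% of all genes. HBA1 was at 11.33 on both against 8.54 to 8.70, and HBZ at 10.00 and 8.51 against 5.05 to 6.07. HBB was below background at 5.72 and 5.75, which alone does not decide the question.

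The lower share of changed lncRNA rows is not accounted for by lower signal alone. The share of changed mRNA rows was 2.06 times that of lncRNA rows, and 1.62 times (95% bootstrap interval 1.42 to 1.85, over rows) when lncRNA rows were weighted to the signal levels of mRNA rows. The spread between arrays was larger among lncRNA rows, with a median SD of 0.57 in parental and 0.49 in resistant arrays. For mRNA rows it was 0.38 and 0.40. These medians are over all rows and were not matched for signal, so the difference in spread may itself follow the lower signal. Whether this spread or the biology of lncRNAs gave the rest was not tested.

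Neighbouring genes changed together, and a candidate explanation is gain or loss of chromosome segments in the resistant line. Along 10195 named genes above background, the largest mean change over 50 neighbours was 1.28 in size, against at most 0.74 in 1000 shuffles of gene order, and 17 windows that do not overlap were past the 95% level of the shuffles. The largest was a fall from TDRKH to HAX1 on chromosome 1, which holds the SPRR genes and has 22% of its genes in the fixed lists, against 7.26% of all genes, so that related genes regulated together could give it as well. The window from IQSEC1 to GOLGA4 on chromosome 3 has 4% in the lists, and 48 of its 50 genes were higher, by a mean of 1.00. From TMEM30A to NR2E1 on chromosome 6, 45 of 50 genes were higher by a mean of 1.05, and from PSCA to TMEM276 on chromosome 8, which includes Ly6 family genes, 44 of 50 were lower, with a mean of −1.16. All 4 windows had the same direction in each of the 3 same-numbered pairs. The windows were picked by their mean over these same arrays, so this is no independent check. DNA was not measured, so copy number itself was not tested.

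The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. In 1 of the 10 splits, the real one, the counts were 1180 changed rows, 727 mRNA rows, 453 lncRNA rows and 10 gene lists. The highest of the other splits were 0, 0, 0 and 6, and at an unadjusted p under 0.05 the highest was 2811 rows against 6837. Of the other splits that part all 3 same-numbered pairs, as the real one does, the highest had 0 changed rows and 5 lists.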
